A study of Homo sapiens with 6 samples.

How the data were processed

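The series holds 6 RNA-seq libraries of U87 cells, an established human glioblastoma line, sorted by flow cytometry from a co-culture, per the labels' protocols. RNA was extracted with TRIzol, mRNA was captured on poly-T beads, cDNA was primed with random hexamers and 150 bp paired-end reads were taken on an Illumina NovaSeq instrument, per the labels. The labels do not say whether the library preparation keeps the strand. The deposited values are raw read counts per gene symbol, whole numbers with no normalization, 1 file per library with 54628 genes in the same order. The submitters' processing notes name DESeq and R 3.6.1. The aligner, the counting program, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. Gene symbols follow RefSeq usage, with the genes of mitochondrial DNA named ND1, CYTB, COX1 and the like, and 51616 of the symbols matched a RefSeq gene table of assembly GRCh38.p14, which was used only for gene classes.

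The titles put each library in its group: 3 libraries of cycling cells that received mitochondria and 3 of cycling cells that did not. Within each group no pair of libraries agreed within sampling noise: chi-square per gene was 3.41 to 3.90 between received replicates, 5.84 between not-received replicates 1 and 3, and 20.6 and 18.8 between not-received replicate 2 and the other libraries of its group. Totals ran from 17879552 to 46392491 counts. A gene at 3 counts stands at 0.0661 CPM in the deepest library and 0.167 CPM in the shallowest; such floors cover counting error only, since reads without molecular identifiers are not independent molecules. Some genes that most cells transcribe strongly had few counts here, among them FBL (1.6 to 1.9 CPM), MALAT1 and SQSTM1, and ID3 had 0 counts in both groups. All of these genes were chosen after their values were seen. How reads shared between genes were counted is not given in the sources used here, so levels of overlapping, antisense or duplicated genes are uncertain.

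Genes were kept with filterByExpr of edgeR 4.0.16 on the group (14100 of the 28833 genes with a count, holding 99.8% to 99.9% of the counts of each library), scaled with TMM factors and tested with glmQLFit (robust) and glmQLFTest in R 4.3.3, received against not received, with the group as the single term. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, and an adjusted p under 0.05 counts as a call. CPM are TMM-scaled, fold changes are received over not received, an SE is the absolute log2 fold change divided by the root of F, and the common coefficient of variation between replicates was 9.47% (5.37% without not-received replicate 2). The share of counts in the 13 mRNAs of mitochondrial DNA was compared with an exact two-sided permutation test, which cannot go under 0.1 with 3 against 3. A set of 40 gene lists with 1023 symbols, all found in the files (some under an alias), was fixed before the data were examined. The 36 lists with at least 5 tested members went through camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists.

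The genes to name were also set before the data were examined. They are the 10 largest increases and the 10 largest decreases among called genes with an average log2 CPM of at least 1 and no overlap between the groups, without clone or LOC names. Up to 4 called members with the largest absolute fold change were taken from each list, among those with an average log2 CPM of at least 1 (where none was called, the 1 or 2 members with the smallest p). ND1, COX1, CYTB, CD274, B2M, MKI67, CDK1, CDKN1A, DHODH, GFAP, SOX2, NES, VIM, PPARGC1A, TFAM, GAP43 and RHOT1 were given whatever their values. Some genes that the rule names are not reported here. From each list's members the text gives a few as examples. Genes named outside this rule are marked as chosen after their values were seen.

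The steps were tested on simulated counts with the means, spread and library sizes of these samples. For received against not received, in a step of 13887 genes, 55 of 100 genes changed 1.5-fold and 78 of 100 genes changed 2-fold were recovered, and 7 of 140 calls were unchanged genes. In the same simulation 0 of 38 random lists of 20 unchanged genes passed camera with the preset correlation and 0 with an estimated one, while a list of genes changed 1.5-fold passed both (adjusted p = 5.08e-43 and 0.0119). The simulated genes vary independently, so this does not test how camera behaves with correlated genes. Far fewer genes were changed in the simulation than were called in the data, and no simulated library was set apart from its group. The shares of genes recovered and falsely called therefore need not hold for these data.

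The alternatives set beforehand were DESeq2's median-of-ratios factors (edgeR's RLE) and library size alone in the same test, DESeq2 1.42.0 at its default settings, limma-voom, no low-count filter, a filter of at least 1 CPM in at least 3 samples, the replicate number as a block, a log2 fold change of at least 1, the genes of mitochondrial DNA left out, camera with an estimated correlation, fry, and each library left out in turn. A correction for GC content and transcript length was added after the data were seen: loess trends (span 0.3) of each library's deviations on GC content and length of the longest GENCODE v29 transcript, for the 90.5% of tested genes with a match, entered the fit as offsets. The counts per list without not-received replicate 2 were also added then. Every library was used, and 0 data columns lacked a sample.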

Results

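Messenger RNA was profiled in U87 cells, an established human glioblastoma cell line, that had been sorted by flow cytometry out of a co-culture. The series title speaks of mitochondria passed from astrocytes to glioblastoma cells, and the labels divide the 6 libraries into cycling cells that had received mitochondria (received, n = 3) and cycling cells that had not (not received, n = 3). The total count was 21314558, 18275336 and 17879552 in the received libraries and 18549585, 46392491 and 21150048 in the not-received libraries. Nothing in the labels says that the replicates were separate cultures, so p-values measure the spread between these samples only. Not-received replicate 2 stood apart from the rest: it was the deepest library, it lay at -44.43 on the first principal component where the other libraries of its group lay at -13.83 and -14.76, and pseudogenes took 0.510% of its counts against 0.163% to 0.221% elsewhere. The comparison asks how the transcriptome of cycling U87 cells that received mitochondria differs from that of cycling cells that did not.

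In cells that had received mitochondria, 12 of 22 chemokines and cytokines (3 lower) and 15 of 22 NF-kB targets were called higher by edgeR. Some genes are on both of these lists. Called lower were 8 of the 13 mRNAs of mitochondrial DNA, 9 of 23 genes of the NRF2 and antioxidant response (1 higher), 15 of 31 G1/S genes and 10 of 18 genes of the unfolded protein response of the endoplasmic reticulum. Camera called these 6 lists at a preset correlation and none of them with an estimated correlation (adjusted p = 0.114 to 0.366). IL1B, which encodes the inflammatory cytokine interleukin-1 beta, rose the most: it stood at 161 ± 11.6 CPM (SD, n = 3) in received cells and 21.4 ± 5.75 CPM in not-received cells, 7.47-fold higher (log2 fold change 2.90 ± 0.19 SE, edgeR quasi-likelihood adjusted p = 4.08e-04). CSF2, the growth factor GM-CSF, rose 4.34-fold, and RRAD, a small GTPase of the RGK family, rose 2.97-fold from 133 ± 15.3 to 395 ± 14.5 CPM. PODXL, the sialomucin podocalyxin, fell by 1.99 on the log2 scale, from 153 ± 14.2 to 38.5 ± 2.25 CPM. CGB5, a chorionic gonadotropin beta chain, fell by 2.20, ATOH8, a basic helix-loop-helix transcription factor, by 1.93, and FGFBP1, a carrier protein of fibroblast growth factors, by 2.14.

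Of 14100 genes tested, 1298 were higher and 1364 lower in received cells at an adjusted p under 0.05 (edgeR quasi-likelihood test), 18.9% of the genes tested. Most changes were small: the median absolute log2 fold change of the called genes was 0.38, and 127 of the higher and 157 of the lower genes changed at least 2-fold. In 5503 genes (39.0%, where chance gives 10%) the received libraries did not overlap with the not-received libraries. Leaving out not-received replicate 2 gave 1356 higher and 1579 lower genes and kept 2287 of the 2662 calls, while leaving out received replicate 1, 2 or 3 gave 606, 604 or 661 higher and 735, 691 or 748 lower genes. With scaling by library size alone the calls split into 1683 higher and 1110 lower genes, that is 60.3% higher against 48.8% with composition factors.

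The other genes with the largest increases were HLA-DQA1, a class II histocompatibility chain (log2 fold change 1.80 ± 0.25 SE), HES7, a transcriptional repressor of the Hairy family (1.75 ± 0.23), CXCL8 (1.73 ± 0.13), TVP23A (1.65 ± 0.20), CXCL2 (1.60 ± 0.07), the readthrough transcript BOLA2-SMG1P6 (1.59 ± 0.32) and HAS3, a hyaluronan synthase (10.8 ± 0.969 against 3.81 ± 0.684 CPM). The other large decreases were DHRS2 (-1.96 ± 0.24), CRYAB, a small heat shock protein (-1.94 ± 0.28), and the processed pseudogenes ANXA2P1, FTH1P23, VDAC1P1 and FTH1P10. The pseudogenes were highest in not-received replicate 2: ANXA2P1 stood at 5.48 CPM there and at 1.03 and 1.58 CPM in the other libraries of its group. Without that library their log2 fold changes shrank, from -3.35 to -2.24 for ANXA2P1, from -2.42 to -1.97 for FTH1P23, from -2.08 to -1.30 for VDAC1P1 and from -1.90 to -1.34 for FTH1P10. The calls of ANXA2P1, VDAC1P1 and FTH1P10 ended when any 1 of the 3 received libraries was left out (highest edgeR adjusted p = 0.162, 0.122 and 0.103). Reads of a pseudogene, of CGB5 or of HLA-DQA1 can also match a near-identical gene, so these values are uncertain.

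**Figure D1:**
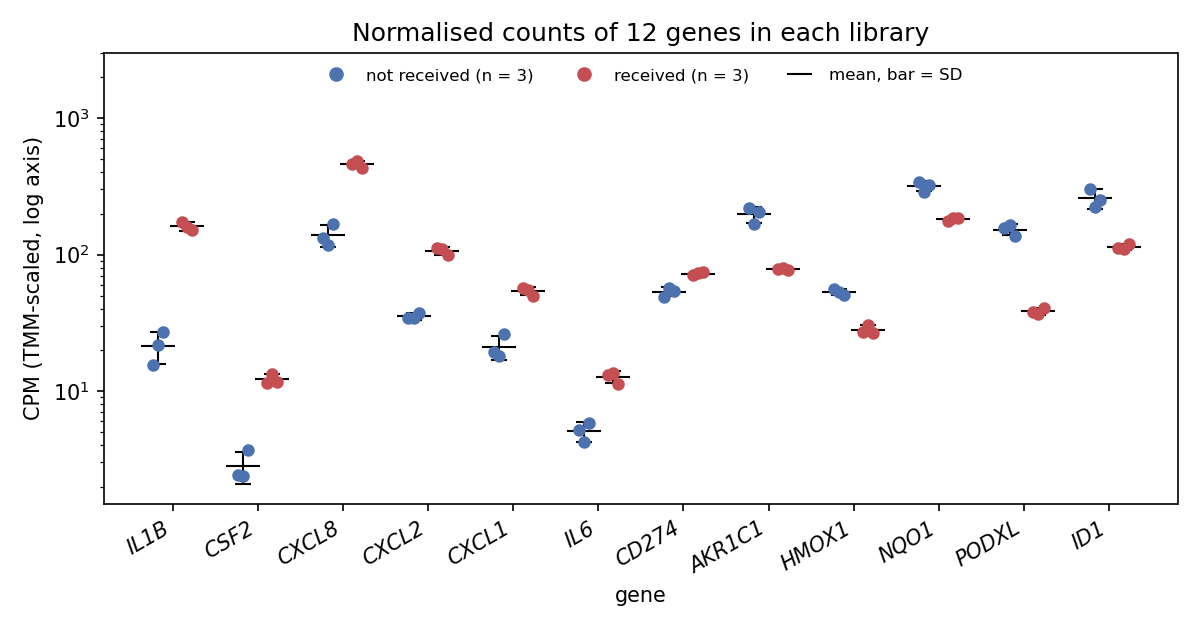
Normalised counts (CPM on a log axis) of 12 named genes in each of the 3 not-received and 3 received libraries; points are libraries, horizontal marks the mean and bars the SD. IL1B lies at 151 to 173 CPM in received cells and at 15.6 to 27.1 CPM in not-received cells, and PODXL, AKR1C1, HMOX1, NQO1 and ID1 are lower in all 3 received libraries than in any not-received library.

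Secreted inflammatory signals had the largest median shift among the gene lists fixed before the data were examined. Of 22 chemokines and cytokines tested, 12 rose and 3 fell (13 and 3 adjusted over the list alone; 11 and 2 by DESeq2), with a median log2 fold change of 1.12. The median was 0.65 with DESeq2 and 0.64 without a low-count filter, fits that take in members with few counts. Besides IL1B and CSF2, the neutrophil-attracting chemokines CXCL8 (458 ± 27.0 against 139 ± 25.2 CPM, n = 3 each) and CXCL2 (107 ± 7.34 against 35.4 ± 2.00 CPM) rose. The 3 members that fell, named after their values were seen, were CSF1 (log2 fold change -0.72 ± 0.07), SPP1 (-0.36 ± 0.06) and IL18 (-1.77 ± 0.48), the last at under 1 CPM in both groups and not called without received replicate 2 or 3 (edgeR adjusted p up to 0.0889). The list passed camera (adjusted p = 3.49e-27; adjusted p = 0.114 with an estimated correlation). CXCL1, CXCL2 and CXCL3 are close paralogs, so the split of reads among them is uncertain.

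NF-kB target genes rose with the cytokines. The NF-kB list shares CXCL1, CXCL2, CXCL8, IL6 and CCL2 with the cytokine list, so the results of these lists are not independent. Of 22 members tested, 15 rose and 0 fell by edgeR's quasi-likelihood test (16 and 1 adjusted over the list alone; 15 and 0 by DESeq2), with a median log2 fold change of 0.45. The largest increases were CXCL8, CXCL2, CXCL1 (1.37 ± 0.13) and IL6 (1.34 ± 0.15), all of them cytokines. Members that are not secreted rose as well, among them the adaptor TRAF1 (1.08 ± 0.10), the apoptosis inhibitor BIRC3 (0.91 ± 0.08) and the NF-kB subunit genes NFKB2 (0.70 ± 0.06) and RELB (0.62 ± 0.08), 4 genes chosen after their values were seen. Camera called the list (adjusted p = 1.28e-24; adjusted p = 0.122 with an estimated correlation). The count of 15 was 15 or 16 with any 1 library left out.

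Counted messenger RNAs encoded by mitochondrial DNA were lower in cells that had received mitochondria. The counts are for human genes and the species of the astrocytes is not given in the sources used here. Whether transcripts of the donated mitochondrial DNA were counted is therefore not known. The 13 mRNAs took 4.11%, 4.04% and 4.22% of the counts in the received libraries and 4.54%, 5.75% and 4.96% in the not-received libraries, 4.13% ± 0.0907 against 5.08% ± 0.614 (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). Cytochrome b mRNA (CYTB) fell by 0.61 ± 0.08 on the log2 scale, from 3012 to 1972 CPM, ND1 by 0.52 ± 0.10 and COX3 by 0.47 ± 0.08. COX1 stood at 10027 ± 506 and 11824 ± 1323 CPM and was not called (log2 fold change -0.24 ± 0.08, edgeR adjusted p = 0.0513). Of the 13, 8 fell and 0 rose (12 and 0 adjusted over the list alone; 12 and 0 by DESeq2), and the list passed camera (adjusted p = 1.16e-07; adjusted p = 0.366 with an estimated correlation). The count of 8 was 5 without any 1 received library and 12 without not-received replicate 1. ND3 also fell, by 0.53 ± 0.14, a call that was lost without any 1 not-received library or without received replicate 3 (adjusted p up to 0.194). The ribosomal RNAs of mitochondrial DNA, chosen after their values were seen, did not go the same way: RNR2 had a log2 fold change of 0.21 ± 0.08 (edgeR adjusted p = 0.0829) and RNR1 of 0.14 ± 0.07 (edgeR adjusted p = 0.185), and together they took 0.564% ± 0.0318 of counts in received and 0.477% ± 0.0508 in not-received libraries (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest possible). Without not-received replicate 2 the difference in the mRNA share was -0.627 instead of -0.960 percentage points, and the count of mRNAs that fell was 4 after correction for GC content and length, a correction chosen after the data were seen.

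**Figure D2:**
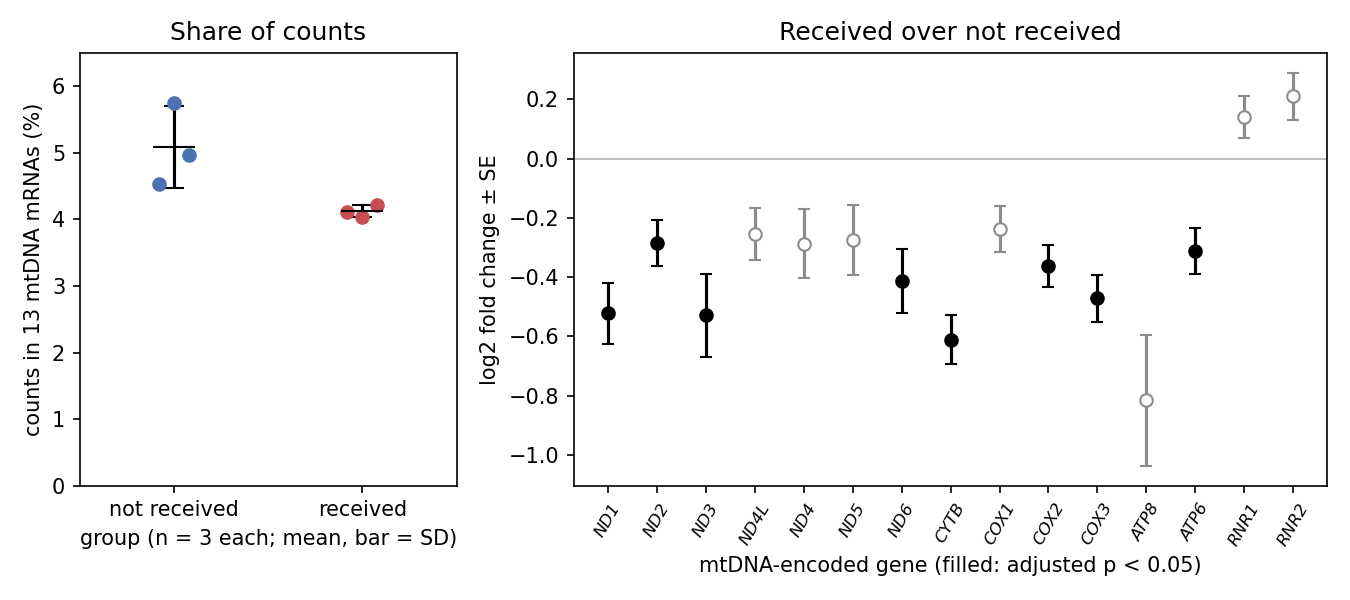
Left, percent of all counts in the 13 mRNAs of mitochondrial DNA in each library of both groups (points; mean and SD, n = 3 each). Right, log2 fold change with SE of each of these mRNAs and of the ribosomal RNAs RNR1 and RNR2, filled where the edgeR adjusted p is under 0.05; all 13 mRNAs lie below 0 and both ribosomal RNAs above it.

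Nuclear genes for the mitochondrial translation machinery and biogenesis rose modestly. Of 46 tested, 15 rose and 0 fell (17 and 0 adjusted over the list alone; 14 and 0 by DESeq2), with a median log2 fold change of 0.16 (camera adjusted p = 6.33e-06; adjusted p = 0.366 with an estimated correlation). Examples were the mitochondrial ribosomal proteins MRPL24 (0.45 ± 0.07) and MRPL15 (0.38 ± 0.07) and TFB1M, which methylates mitochondrial ribosomal RNA (0.39 ± 0.08). Without received replicate 1, 2 or 3, the count was 7, 8 or 6. TFAM, which packages mitochondrial DNA, had a log2 fold change of 0.12 ± 0.07, and PPARGC1A, the coactivator of mitochondrial biogenesis, of 0.15 ± 0.26 (edgeR adjusted p = 0.267 and 0.716). Nuclear genes of oxidative phosphorylation went both ways, with 4 of 74 higher and 7 lower (2 and 5 adjusted over the list alone; camera adjusted p = 0.724), among them CYC1 (0.28 ± 0.06) and NDUFA1 (-0.38 ± 0.09). The balance turned with scaling by library size alone (10 higher and 4 lower) and with the replicate number as a block (9 higher and 8 lower). It was 6 and 5, 4 and 10, and 7 and 4 without not-received replicate 1, 2 and 3, and 1 and 4, 1 and 1, and 0 and 1 without received replicate 1, 2 and 3. The call of CYC1 was lost without received replicate 3 and that of NDUFA1 without received replicate 2 or 3. In the tricarboxylic acid cycle 3 of 23 genes rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.0972), led by SUCLG2 (0.50 ± 0.09) and PC, pyruvate carboxylase (-0.43 ± 0.08). The count of 3 was 1 without not-received replicate 1 or any 1 received library and 5 with scaling by library size alone, and the list passed without not-received replicate 3 (camera adjusted p = 0.0366 at the preset correlation; 0.43 with an estimated correlation over all 6 libraries). Genes of mitochondrial dynamics and mitophagy split 3 up and 5 down of 25 (3 and 5 adjusted over the list alone; camera adjusted p = 0.743). These were 3 and 1 with scaling by library size alone, 2 and 2, 3 and 3, or 3 and 2 without not-received replicate 1, 2 or 3, and 0 and 2, 1 and 1, or 0 and 1 without received replicate 1, 2 or 3. OPTN, a mitophagy receptor, had a log2 fold change of -0.44 ± 0.07. Genes linked to mitochondrial transfer and cell protrusions split 2 up and 3 down of 22 (2 and 3 adjusted over the list alone; camera adjusted p = 0.989), among them GJA1, the gap junction protein connexin 43 (0.38 ± 0.07), and SDC2 (-0.36 ± 0.07). The 3 that fell were 1 without not-received replicate 3 or any 1 received library. RHOT1, the mitochondrial GTPase Miro1, had a log2 fold change of 0.15 ± 0.08 and GAP43 of 0.17 ± 0.23 (edgeR adjusted p = 0.243 and 0.644).

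Genes of the NRF2 and antioxidant response fell. Of 23 members 9 fell and 1 rose (9 and 1 adjusted over the list alone), with a median log2 fold change of -0.10, or -0.07 with scaling by library size alone (camera adjusted p = 8.52e-09; adjusted p = 0.161 with an estimated correlation). AKR1C1, an aldo-keto reductase with close paralogs, fell from 198 ± 26.6 to 78.8 ± 1.25 CPM, HMOX1, heme oxygenase 1, from 53.4 ± 2.42 to 28.1 ± 2.27 CPM, and NQO1 from 318 ± 26.4 to 182 ± 5.19 CPM (n = 3 each). The ferritin light chain FTL fell by 0.57 ± 0.06 on the log2 scale. The member that rose, named after its value was seen, was SOD2 (0.39 ± 0.07), mitochondrial superoxide dismutase, which is also on the NF-kB list.

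Genes of the unfolded protein response of the endoplasmic reticulum fell, with 10 of 18 lower and 0 higher by edgeR (10 and 0 adjusted over the list alone; 10 and 0 by DESeq2) and a median log2 fold change of -0.30. SDF2L1 fell by 0.58 ± 0.11, CRELD2 by 0.49 ± 0.07, DNAJB11 by 0.46 ± 0.06 and SYVN1, a ubiquitin ligase, by 0.45 ± 0.09 (camera adjusted p = 1.20e-07 for the list; adjusted p = 0.161 with an estimated correlation). In the lysosome and autophagy list 10 of 27 genes fell and 2 rose (10 and 2 adjusted over the list alone; camera adjusted p = 0.00186; adjusted p = 0.218 with an estimated correlation), with the protease CTSD down by 0.52 ± 0.06, NPC2 by 0.49 ± 0.06, TPP1 by 0.49 ± 0.07 and GPNMB by 1.76 ± 0.21. The count of 10 was 6, 6 or 7 without received replicate 1, 2 or 3, and the calls of the 2 that rose, TFEB and SQSTM1, named after their values were seen, were each lost in 5 of the 6 fits with 1 library left out. SQSTM1 had only 58 counts in all in received and 37 in not-received cells, so its level is uncertain. Heat shock proteins fell in 5 of 15 cases and rose in 0 (5 and 0 adjusted over the list alone), among them CRYAB, HSPB1 (-0.30 ± 0.06) and DNAJA1 (-0.30 ± 0.05). The count of 5 was 3 without any 1 received library. Camera called that list (adjusted p = 0.0204; adjusted p = 0.254 with an estimated correlation), but not without not-received replicate 1 (adjusted p = 0.0773). The integrated stress response list had 5 of 23 lower and 1 higher (8 and 1 adjusted over the list alone; camera adjusted p = 0.0741). ATF5 had a log2 fold change of -0.61 ± 0.10 and NUPR1 of -0.60 ± 0.08. The single higher member was not called without any 1 received library. The list passed without not-received replicate 2 (camera adjusted p = 0.0156; 8 lower and 1 higher) and without received replicate 1 (camera adjusted p = 0.0309), each at the preset correlation. With an estimated correlation over all 6 libraries the camera adjusted p was 0.575.

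Genes of the G1/S transition fell while those of G2/M did not. Of 31 G1/S genes 15 fell and 0 rose (20 and 0 adjusted over the list alone; 15 and 0 by DESeq2), with a median log2 fold change of -0.23 (camera adjusted p = 8.52e-09; adjusted p = 0.192 with an estimated correlation). E2F1, a transcription factor of S-phase genes, fell by 0.44 ± 0.06, the DNA repair enzyme gene UNG by 0.42 ± 0.08 and the replication helicase subunit gene MCM4 by 0.38 ± 0.05. Without received replicate 1 or 2 the count was 8 or 10. Of 35 G2/M genes 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.17). HMMR had a log2 fold change of 0.26 ± 0.06 and PTTG1 of 0.27 ± 0.06. The 5 that rose were 0, 1 or 2 without received replicate 1, 2 or 3. Received replicate 1 was needed for both calls and received replicate 2 for that of HMMR. MKI67 stood at 594 ± 19.2 and 697 ± 128 CPM and CDK1 at 332 ± 15.9 and 281 ± 33.5 CPM in received and not-received cells (edgeR adjusted p = 0.213 and 0.0513). The difference between the lists was not tested.

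Targets of MYC and of p53 rose in part. Of 26 MYC targets 7 rose and 0 fell (8 and 0 adjusted over the list alone; 7 and 0 by DESeq2). ODC1, the first enzyme of polyamine synthesis, had a log2 fold change of 0.67 ± 0.06 and the transferrin receptor TFRC of 0.36 ± 0.06. Camera called the MYC targets (adjusted p = 7.39e-05; adjusted p = 0.366 with an estimated correlation). The count was 13 without not-received replicate 2 and 4 without received replicate 3. Of 21 p53 targets 8 rose and 0 fell (8 and 0 adjusted over the list alone; 7 and 0 by DESeq2), led by PLK3 (0.60 ± 0.10), the death receptor FAS (0.58 ± 0.07) and DDB2 (0.31 ± 0.06; camera adjusted p = 0.00303 for the list; adjusted p = 0.366 with an estimated correlation). Without received replicate 1, 2 or 3 the count was 4, 5 or 5. CDKN1A, the cell cycle inhibitor p21, had a log2 fold change of 0.18 ± 0.06, with a call (edgeR adjusted p = 0.0387) that was lost in 5 of the 6 fits with 1 library left out. Quiescence and arrest genes split 3 up and 5 down of 25 (3 and 5 adjusted over the list alone; camera adjusted p = 0.358). These were 3 and 3 with scaling by library size alone, 2 and 3 without not-received replicate 1, 1 and 5 without not-received replicate 3, and 1 and 1, 1 and 2, or 1 and 1 without received replicate 1, 2 or 3. KLF2 had a log2 fold change of -1.28 ± 0.09 and TXNIP of 0.38 ± 0.08. Cytosolic ribosomal proteins had 10 of 70 higher and 0 lower (9 and 0 adjusted over the list alone; 15 and 2 by DESeq2), among them RPL4 (0.22 ± 0.05), whose call needed received replicates 1 and 3. The count of 10 was 18 with scaling by library size alone and 0, 4 or 0 without received replicate 1, 2 or 3. Camera called that list (adjusted p = 0.0204; adjusted p = 0.784 with an estimated correlation), but not without not-received replicate 2 (adjusted p = 0.294) or received replicate 1 or 3 (0.146 and 0.0832). Replication-dependent histones had 2 of 20 higher, H1-2 (0.86 ± 0.13) and H2BC12 (0.65 ± 0.11), and 0 lower (2 and 0 adjusted over the list alone; camera adjusted p = 0.534).

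Glycolytic genes fell and fatty acid oxidation genes shifted slightly upward. Of 22 glycolytic genes 8 fell and 2 rose (13 and 2 adjusted over the list alone), with a median log2 fold change of -0.20 (camera adjusted p = 5.78e-04; adjusted p = 0.366 with an estimated correlation). PDK1, a kinase that inhibits pyruvate dehydrogenase, fell by 0.57 ± 0.07, the phosphofructokinase gene PFKL by 0.33 ± 0.06 and PFKFB3, which makes an activator of phosphofructokinase, by 0.32 ± 0.06. The 2 that rose were PFKM (0.29 ± 0.06) and LDHB (0.21 ± 0.06), named after their values were seen. The call of LDHB was lost in 3 of the fits with 1 library left out. The count of 8 was 12 without not-received replicate 2, 5 without received replicate 2 and 4 without received replicate 3. In fatty acid oxidation CPT1A (0.38 ± 0.07), ACAA2 (0.33 ± 0.08) and ECI2 (0.32 ± 0.08) rose of 19 genes and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.0204; adjusted p = 0.43 with an estimated correlation), and the list was not called without not-received replicate 2 (adjusted p = 0.0985). The count of 3 was 1 without received replicate 2 and 5 with scaling by library size alone. ACAA2 lost its call without received replicate 1 or 2 and ECI2 without received replicate 2. Hypoxia genes had 1 of 20 higher and 5 lower (2 and 5 adjusted over the list alone; camera adjusted p = 0.17). KDM3A had a log2 fold change of -0.44 ± 0.08. The list's median was -0.12 and its mean 0.03, and the median was -0.22, -0.02 or -0.07 without received replicate 1, received replicate 3 or not-received replicate 3. It passed without received replicate 1 (camera adjusted p = 0.00148 at the preset correlation; 0.784 with an estimated correlation over all 6 libraries). Hypoxia counts were 3 and 3 with scaling by library size alone, 0 and 4 or 2 and 3 without not-received replicate 2 or 3, and 0 and 3 or 2 and 2 without received replicate 2 or 3. Cholesterol synthesis split 3 up and 4 down of 24 (4 and 5 adjusted over the list alone; camera adjusted p = 0.902). Those counts were 1 and 5 without not-received replicate 1, 0 and 3 without received replicate 1 or 2, and 1 and 2 without received replicate 3. LSS had a log2 fold change of -0.58 ± 0.13, a call lost without received replicate 3. Pyrimidine and one-carbon metabolism split 2 up and 2 down of 19 (2 and 2 adjusted over the list alone; camera adjusted p = 0.633). They were 1 and 2, 1 and 4, or 1 and 2 without not-received replicate 1, 2 or 3, 0 and 2 without received replicate 1 or 2, and 0 and 0 without received replicate 3. ALDH1L2 had a log2 fold change of -0.35 ± 0.08, a call lost without received replicate 3. DHODH, the pyrimidine synthesis enzyme of the inner mitochondrial membrane, stood at 22.2 ± 0.943 and 19.9 ± 2.14 CPM (edgeR adjusted p = 0.243).

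Among genes of immune recognition, CD274, which encodes the checkpoint ligand PD-L1, rose from 53.5 ± 4.05 to 72.6 ± 1.81 CPM (n = 3 each; log2 fold change 0.44 ± 0.07, edgeR adjusted p = 9.88e-04), while CD24 fell from 80.8 ± 8.01 to 46.6 ± 1.42 CPM. Checkpoint and immune suppression genes had 3 of 21 higher and 2 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.777). The 3 were 1 without received replicate 1 or 2, and the 2 were 1 without received replicate 2. Antigen presentation genes had 4 of 17 higher and 2 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.124; fry adjusted p = 0.0489), among them CIITA, the regulator of class II genes (0.61 ± 0.09), CD74, the class II invariant chain (0.35 ± 0.06), HLA-DPB1 (0.40 ± 0.09) and the chaperone CALR (-0.42 ± 0.06). The other member that fell was HLA-C, a class I heavy chain named after its values were seen. HLA-C lay under the average log2 CPM of 1 that the naming rule required. How reads shared with other class I genes were counted is not given, so its level is uncertain. The log2 fold change of HLA-C ran from -2.66 to -1.39 with 1 library left out, and 3 of those fits lost its call. The 2 that fell were 1 without any 1 received library. B2M, the light chain of class I molecules, stood at 226 ± 30.2 and 168 ± 23.5 CPM (edgeR adjusted p = 0.0676). Interferon-response genes had 1 of 33 higher and 3 lower (1 and 3 adjusted over the list alone; camera adjusted p = 0.724), IRF1 at 0.45 ± 0.08 and SAMD9 at -0.38 ± 0.08. That balance was 5 and 3 with scaling by library size alone, 3 and 3 with limma-voom, the CPM filter or the GC and length correction, and 2 and 3 without not-received replicate 3. Nucleic acid sensors had 5 of 15 higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.0624; fry adjusted p = 0.0162). The 5 were 2 without received replicate 1 or 3. The DNA sensor AIM2 had a log2 fold change of 0.76 ± 0.13 and MAVS of -0.39 ± 0.08. The list passed without not-received replicate 2 (camera adjusted p = 0.041) or received replicate 2 (0.047) at the preset correlation. With an estimated correlation over all 6 libraries the camera adjusted p was 0.366.

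Genes of mTORC1 and growth factor signalling rose in 7 of 25 cases and fell in 4 (9 and 5 adjusted over the list alone), with HGF, the ligand of MET, at 1.44 ± 0.14, EREG, a ligand of the EGF receptor, at 0.90 ± 0.08 and HBEGF at 0.50 ± 0.08, and the feedback inhibitor SPRY4 at -0.65 ± 0.10. The 4 that fell were 2 without received replicate 3. Camera called the list (adjusted p = 0.0204; adjusted p = 0.43 with an estimated correlation), but not without not-received replicate 1 (adjusted p = 0.0773). Immediate early genes fell in 7 of 25 cases and rose in 2 (9 and 4 adjusted over the list alone), with KLF2, CCN2 (-0.93 ± 0.09), CCN1 (-0.61 ± 0.09) and PPP1R15A (-0.50 ± 0.09) lowest and JUNB, chosen after its value was seen, at 0.36 ± 0.07. The 2 that rose were 1 without not-received replicate 1 or any 1 received library. Camera called that list as lower (adjusted p = 0.0204; adjusted p = 0.43 with an estimated correlation), while its median was -0.06 and its mean 0.00. The call was lost without not-received replicate 2 (adjusted p = 0.069) and after the GC and length correction (adjusted p = 0.298). Mesenchymal genes split 6 up and 8 down of 33 (10 and 9 adjusted over the list alone; camera adjusted p = 0.724). The split was 10 and 9 without not-received replicate 2, 10 and 8 with scaling by library size alone, and 3 and 5, 3 and 7, or 3 and 6 without received replicate 1, 2 or 3. MMP3, a matrix protease, had a log2 fold change of -1.37 ± 0.11, CHI3L1 of -0.90 ± 0.10 and THBS1 of -0.92 ± 0.11. The intermediate filament gene VIM rose from 3918 ± 333 to 4680 ± 113 CPM, a call lost without any 1 received library (edgeR adjusted p up to 0.0779). Stem and progenitor genes split 5 up and 3 down of 15 (5 and 5 adjusted over the list alone; camera adjusted p = 0.358). Here the split was 2 and 4, 3 and 3, or 2 and 3 without not-received replicate 1, 2 or 3, and 1 and 3, 1 and 3, or 2 and 3 without received replicate 1, 2 or 3. NES, nestin, had a log2 fold change of 0.46 ± 0.09, ID1 of -1.18 ± 0.11 and L1CAM of -0.68 ± 0.10.

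**Figure D3:**
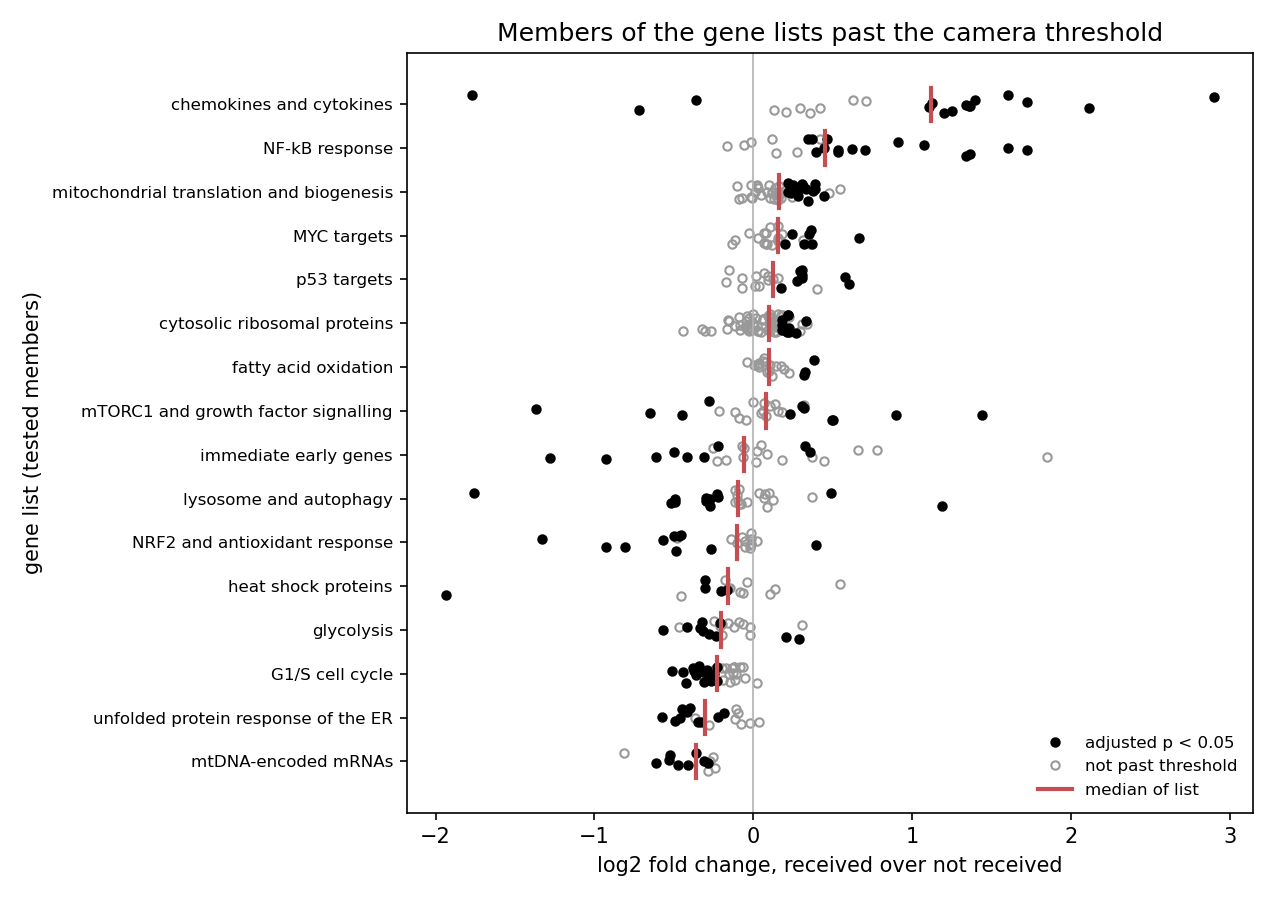
Log2 fold change (received over not received) of each tested member of the 16 gene lists that passed camera at the preset correlation; filled points have an edgeR adjusted p under 0.05, open points do not, and the vertical mark is the list's median. The medians run from -0.36 for the mRNAs of mitochondrial DNA to 1.12 for chemokines and cytokines.

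Markers of other cell types were also followed. GFAP, the astrocyte intermediate filament, stood at 0.328 ± 0.115 CPM in received and 0.39 ± 0.179 CPM in not-received cells (19 and 30 counts in all), and SOX2 at 0.607 ± 0.20 and 0.102 ± 0.0993 CPM (36 and 11 counts), both under the low-count filter, where 3 counts correspond to 0.0661 to 0.167 CPM. Astrocyte markers had 2 of 11 higher and 2 lower (2 and 3 adjusted over the list alone; camera adjusted p = 0.382), with GJA1 (0.38 ± 0.07) and SOX9 (0.31 ± 0.08) the 2 that rose and CLU (-0.36 ± 0.06) among those that fell. Astrocyte counts were 2 and 1 without not-received replicate 3 or received replicate 2, and 1 and 1 without received replicate 1 or 3. Neuron markers had 2 of 7 lower and 0 higher (2 and 0 adjusted over the list alone; camera adjusted p = 0.112), TUBB3 (-0.52 ± 0.07) and SNAP25 (-0.49 ± 0.12), the last not called without received replicate 1. Fibroblast and pericyte markers had 4 of 13 higher and 0 lower (4 and 0 adjusted over the list alone; camera adjusted p = 0.0972). KCNJ8 had a log2 fold change of 0.99 ± 0.17 and DCN of 0.85 ± 0.17, and the list passed without not-received replicate 2 (camera adjusted p = 0.0446 at the preset correlation; 0.43 with an estimated correlation over all 6 libraries). Its count of 4 was 2 without not-received replicate 1 or received replicate 3. Too few members were tested for camera in the other lists. Of 4 microglia and macrophage markers 2 rose, CD68, a lysosomal protein (481 ± 8.48 against 374 ± 21.9 CPM), and CD74, and 0 fell (2 and 0 adjusted over the list alone). Of 3 oligodendrocyte markers MYRF rose (0.65 ± 0.14) and 0 fell (1 and 0 adjusted over the list alone). Of 4 endothelial and 3 T and NK cell markers 0 were called by edgeR (0 adjusted over the list alone; 0 by DESeq2), with 1 and 0 at an unadjusted p under 0.05, and with KDR at 0.29 ± 0.12 and IL7R at -0.12 ± 0.09. Leaving out not-received replicate 2 gave 1 lower microglia or macrophage marker, 1 lower oligodendrocyte marker and 1 higher endothelial marker.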

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

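The correction for GC content and length and the counts per list without not-received replicate 2 were chosen after seeing the data; the other alternatives were set before. The count of higher genes (1298) lay between 1086 and 1683, and that of lower genes (1364) between 1110 and 1518, under RLE factors, library size alone, DESeq2, limma-voom, the CPM filter, the replicate block, the genes of mitochondrial DNA left out and the GC correction; without a filter 1456 were higher and 2084 lower, where the larger number of genes tested (28833) includes many at few counts. A log2 fold change of at least 1 left 127 and 157. With 1 library left out, the counts ran from 604 to 1356 higher and from 691 to 1579 lower, lowest without a received library; the cause was not tested. The replicate block gave 1252 higher and 1384 lower genes, shared 2420 calls and left the count of lists at 16. Deviations of same-numbered libraries from their group means correlated at -0.20, -0.07 and 0.05 across genes, and no library correlated best with its own number. With 3 libraries per group and not-received replicate 2 set apart, these correlations cannot decide whether same-numbered libraries were paired. The labels name no pairs, so the numbers were not taken as pairs. DESeq2 shared 2196 of the 2662 calls and limma-voom 2552. The 16 lists that passed camera were 14 to 17 with 1 library left out, 16 under RLE factors and the CPM filter, 20 with fry, and 0 with an estimated correlation (7 of 36 at an unadjusted p under 0.05; lowest adjusted p 0.114; median estimated correlation 0.113); the list tests therefore rest on the preset correlation. Fry also called antigen presentation, nucleic acid sensing, the tricarboxylic acid cycle, quiescence and the fibroblast and neuron markers, which camera did not, and did not call immediate early genes or cytosolic ribosomal proteins. The difference in the share of mRNAs of mitochondrial DNA (-0.960 percentage points) kept its direction in all alternatives, from -1.23 to -0.627. Of 187 called genes followed by name, 121 kept their call and direction in every alternative that gave a value and 66 lost the call in at least 1, 65 of them when a library was left out. The uncalled genes PPARGC1A (up to 0.34) and GAP43 (up to 0.40) changed sign with 1 library left out: PPARGC1A at -0.016 without not-received replicate 1 and GAP43 at -0.013 without received replicate 3; their fold changes lie within their SE of 0. Depth limits what can be said of genes under 1 CPM, such as GFAP and SOX2, which were not tested.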

Other observations

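The gene groups in this paragraph were put together after the fold changes were seen, so their counts describe these libraries and are no independent test. Genes known as targets of BMP and SMAD signalling fell in received cells. The group had 17 members, of which only 13 were tested. Of the 13 tested, 11 were called lower by edgeR (11 without not-received replicate 2), with a median log2 fold change of -1.18, while HEY1 (-0.60) and MSX1 (0.04) were not called. SMAD6, an inhibitor of BMP signalling, stood at 7.68 ± 0.578 CPM in received and 24.2 ± 3.66 CPM in not-received cells (SD, n = 3 each; log2 fold change -1.65 ± 0.12 SE). ID1, ID2, SMAD9 and SMAD7 had log2 fold changes of -1.18, -1.12, -1.30 and -0.91, and NOG, BAMBI, DLX2 and ATOH8 of -1.27, -0.83, -1.63 and -1.93.

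A group of class II genes was likewise chosen after its values were seen and is partly on the antigen presentation list. It had 11 members, of which only 6 were tested. All 6 were called higher by edgeR. They were the 4 histocompatibility chains HLA-DRB1 (log2 fold change 0.32 ± 0.08 SE), HLA-DPB1 (0.40 ± 0.09), HLA-DQB1 (1.07 ± 0.11) and HLA-DQA1 (1.80 ± 0.25), the invariant chain CD74 (0.35 ± 0.06) and the regulator CIITA (0.61 ± 0.09). HLA-DRB1 lost its call without any 1 received library. The chorionic gonadotropin beta genes and KRT14 were also chosen after their values were seen. Of 6 gonadotropin genes only 4 were tested. All 4 fell, CGB8 from 41.7 ± 8.24 to 14.5 ± 2.69 CPM, and CGB7 (-0.83) lost its call without not-received replicate 1 or received replicate 1 or 2. KRT14, a keratin of basal epithelium, fell by 1.88 ± 0.12 on the log2 scale. The gonadotropin and class II genes have close copies, so the split of reads within each family is uncertain.

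All tests of the mitochondrial and cytokine patterns below were chosen after the results were seen, except that the bound for the GC and length correction and the count of splits were set before their values were computed. The counted mRNAs of mitochondrial DNA were lower in received cells (median log2 fold change of the 13 mRNAs -0.36, median SE 0.0881). Whether transcripts of the donated mitochondrial DNA were among those counted is not known, since the species of the astrocytes is not given. The values argue against not-received replicate 2 as the whole cause, since the median was -0.28 (median SE 0.0548) without it. After the correction for GC content and length the median was -0.36, so the trends fitted over all genes did not account for it. In that fit 4 instead of 8 mRNAs were called and the median SE rose to 0.119, and the reason for the lost calls was not tested. The median plus 2 median SE was -0.119, narrowly under the bound of -0.1. That SE is the median over single mRNAs, not the SE of a median of mRNAs that vary together (estimated correlation 0.755). An effect of GC content or length is thus not excluded. Equal loss of all transcripts of mitochondrial DNA stays open: RNR2, chosen after its value was seen, had a log2 fold change of 0.21 ± 0.08 and was not called, and poly-T beads do not select ribosomal RNA, so its level here does not decide whether it was lost; a change in mRNA turnover linked to receipt of mitochondria may also account for the pattern and was not tested.

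Cytokine and NF-kB genes were higher in received cells, with IL1B up by 139 ± 7.45 CPM (SE). RNA carried over from astrocytes was not excluded. The 17 astrocyte markers under 5 CPM in not-received cells moved by -1.72 ± 0.463 CPM in sum, from 9.336 to 7.614 CPM. GFAP stood at 0.328 and 0.39 CPM in received and not-received cells, and AQP4 had 0 counts in both groups. These low markers thus showed no gain. The bound of the test was scaled to the rise of IL1B and lay above the whole sum, so the test could not exclude a smaller carry-over. GJA1 (228 to 297 CPM) and SOX9 (19.1 to 23.8 CPM), both above 5 CPM in not-received cells and so outside that sum, rose. The sort was for U87 cells, and the species of the astrocytes is not given in the sources used here. The 14 microglia and macrophage markers under 5 CPM moved by 0.123 ± 0.301 CPM in sum, from 0.826 to 0.949 CPM, which is no clear gain. The bound here was also scaled to the rise of IL1B, and whether such markers would rise in step with IL1B was not tested. Such cells are thus not excluded. CD68 and CD74, both above 5 CPM in not-received cells and so outside that sum, rose. Fibroblast and pericyte markers, with 4 of 13 called higher and 0 lower, were not weighed in this way. Stress of sorting and handling stays open: immediate early and heat shock genes went both ways (median log2 fold change -0.079, SD 0.579 over 40 genes), and the rule for this test was changed after a first rule, which used the median SE, had counted against stress. Cells were grouped by the sort and not assigned at random, so a difference that preceded the transfer and a response to the mitochondria could each account for the pattern, and neither was tested.

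The 6 samples can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. For the counts of higher and of lower genes 1 of the 10 splits, the real one, gave a result as large, with 1298 higher and 1364 lower genes. The other 9 splits gave 0 in either direction by edgeR, with at most 423 genes at an unadjusted p under 0.05 (4695 in the real split), and DESeq2 called at most 1 (2535 in the real split). Each of these 9 splits mixes libraries of both groups, so the group difference adds to the spread within its groups and lowers its calls. Their counts therefore do not measure what chance alone would give. For the gene lists 1 of the 10 splits, again the real one, gave 16 lists by camera at the preset correlation, and the highest of the others gave 14. With an estimated correlation camera called 0 lists in every split, the real one included, where 7 lists had an unadjusted p under 0.05. Calls of lists at the preset correlation thus also arose in splits that mix the groups. Such splits still hold part of the difference between received and not-received cells, so these calls do not measure a rate of false calls.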
